A study of Mus musculus with 6 samples.

How the data were processed

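Uteri of female mice aged 2 weeks were profiled on Affymetrix expression arrays, with 3 arrays of the genotype labelled Arid1a f/f and 3 of the genotype labelled Arid1a d/d. Per the labels, biotin-labelled cRNA was made from 500 ng of total RNA for each array. The deposited table holds 1 intensity per probe set and array on a linear scale, and RMA is named for it in the submitters' processing notes, without a version or settings. RMA corrects the background, brings arrays to a shared distribution and summarises the probes of a probe set, so small differences at the dim end are compressed towards the background. The scanner output, the detection calls and any scan date were not used here, and no genome build is given in the sources used here, so no coordinates are printed.

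The analysis had been designed for log2 values, but the deposited intensity values are linear, with a median of 6.45, so log2 was taken of every value with no added constant. All 41420 probe sets were tested and no column of values was left out. The platform annotation gave exactly 1 gene symbol to 31562 probe sets, several to 830 and none to 9028. A gene was represented by its probe set with the highest mean over the 6 arrays among those with 1 symbol, which gave 16813 genes. The table held 0 probe sets with the prefix of Affymetrix controls.

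The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with no intensity trend and no robust estimation, 2-sided, no covariate). Benjamini-Hochberg adjustment ran over all probe sets or all genes, with a threshold of 0.05, and every difference is Arid1a d/d minus Arid1a f/f on the log2 scale. The fit had 4 residual degrees of freedom per gene and 4.19 from the prior. The number of arrays limits the precision. The labels do not say whether the arrays of a genotype came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

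Before the data were examined, 34 gene lists with 555 entries were fixed, covering markers of the cell types that a dissected uterus could hold, signalling pathways, and general cell states. Of their 529 distinct genes, 412 were measured. For each list the members past the threshold were counted over all genes and adjusted over the list alone, and limma's camera was run with a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Camera with a correlation estimated per list and fry, which asks whether a list's genes move one way on balance, were alternatives.

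The rule for named genes was also fixed before the data were examined. It takes Arid1a and Foxa2, then the 15 genes with the largest rise and the 15 with the largest fall among genes past the threshold whose d/d values all lay beyond all f/f values and whose mean in the higher group exceeded 2.69, the median over all probe sets. Clone and predicted-gene symbols were counted but passed over. Up to 4 members of smallest p were then named per list, or up to 2 where neither the list nor a member passed. Pgr and Esr1 are named outside that rule, after their values were seen, as are Etv5, Il17rd, Cgn, Ocln, Marveld2, Dsp and the genes named with them.

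The steps were tested on simulated data with the spread of these arrays. Over 16813 simulated genes, 18 of 50 changed 1.5-fold were recovered, 47 of 50 changed 2-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 13 false calls among 178. Over 41420 simulated probe sets the numbers recovered of 50 were 9, 41, 48 and 50, with 5 false calls among 153. A simulated shift of 0.5 in the epithelium list was recovered, and 0 of the 33 other lists were called. The simulated genes varied independently of one another. In the real arrays the estimated correlation was 0.910 within the cell cycle list and 0.602 within the fat list. The simulation therefore does not show how often camera calls such lists falsely.

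The alternatives were a replicate block, an intensity trend with robust variance, array weights, a repeated quantile normalization, median centring, leaving out probe sets under the 40th percentile of mean level, leaving out probe sets with the suffix _x_at, each array left out in turn, other thresholds, the mean of all probe sets of a gene, and the other list tests. Leaving out both arrays numbered 1 and the covariates for cell cycle and fat genes were chosen after seeing the data.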

Results

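Transcript levels were measured in uteri of intact female mice aged 2 weeks, with 3 arrays labelled Arid1a f/f and 3 labelled Arid1a d/d. Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. In the usual notation f stands for a floxed allele and d for a deleted one. The median intensity of an array lay between 6.34 and 6.59, and the correlation between arrays over all probe sets lay between 0.987 and 0.995. The study's title concerns the need for Arid1a in the development of endometrial glands, and the comparison asks which transcripts differed between the genotypes at this age.

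Arid1a itself was lower in d/d uteri. Its 1 probe set measured 7.61 ± 0.09 (SD, n = 3) in f/f and 7.03 ± 0.05 (SD, n = 3) in d/d on the log2 scale. The log2 difference was -0.58 ± 0.09 (SE), with a limma adjusted p of 0.0342 over all probe sets, and all d/d arrays lay below all f/f arrays. The d/d level was 0.667 of the f/f level. The labels do not say which part of the gene is deleted, so whether this probe set checks the genotype is open. Without any 1 of f/f 1, f/f 2, f/f 3, d/d 2 or d/d 3 the adjusted p over genes rose above the threshold, up to 0.111, with log2 differences of -0.62 to -0.53.

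Foxa2 and Cxcl15, 2 genes of the uterine glands, were lower in d/d uteri. Foxa2, a transcription factor of the glandular epithelium, fell 2.66-fold, from 4.50 ± 0.28 to 3.09 ± 0.20 (SD, n = 3; log2 difference -1.41 ± 0.16 SE; limma adjusted p = 0.0116). Cxcl15, a chemokine secreted by the glands, fell 13.1-fold, from 5.58 ± 0.73 to 1.87 ± 0.23 (log2 difference -3.71 ± 0.33 SE; limma adjusted p = 0.00538), and its other probe set fell 4.59-fold. Its d/d level lay below the median of all probe sets, 2.69, where background limits the fold. Of the 10 measured markers of glandular epithelium, 0 rose, 2 fell and 8 did not pass, and adjusted over the list alone the same 2 passed. Prss28, Lif, Slc18a2 and Wfdc3 lay below 2.69 in both genotypes, Prss28 at 1.64 and 1.37, and Ttr had a log2 difference of -0.14. The list was lower by camera (median log2 difference -0.15; adjusted p = 0.00394), with adjusted p = 0.453 with an estimated correlation. With members held by another list left out the adjusted p was 0.250, but this removes Foxa2 and Cxcl15, the 2 members that passed. Leaving out f/f 2, f/f 3, d/d 2 or d/d 3 ended the Foxa2 call, with adjusted p up to 0.0834, and Cxcl15 passed without each array.

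Hedgehog pathway genes were lower as well. Ihh, the hedgehog ligand of the uterine epithelium, fell 2.80-fold (log2 difference -1.49 ± 0.15 SE; limma adjusted p = 0.00918). Its levels in d/d 2 and d/d 3, 2.50 and 2.60, lay below 2.69, where background limits the fold. Gli1, a transcription factor that responds to the signal, fell by 0.96 ± 0.10 and Ptch1, the receptor and a target of the pathway, fell by 0.95 ± 0.15 on the log2 scale (SE; limma adjusted p of 0.00975 and 0.0390). Of 13 measured hedgehog genes, 3 fell, 0 rose and 10 did not pass, and 4 fell adjusted over the list alone, with Hhip at -0.57 as the fourth. Camera gave a median log2 difference of -0.17 and adjusted p = 7.28e-05, with adjusted p = 0.453 with an estimated correlation. Ptch1 has 3 probe sets, of which 1 passed, and their mean gave a log2 difference of -0.31 (adjusted p = 0.196). The probe sets that did not pass lay below 2.69, the median of all probe sets, in both genotypes, where background limits what they can show. Among receptors and progesterone-responsive genes, Ihh and Ptch1, which the hedgehog list also holds, were the 2 of 16 that fell. Adjusted over the list alone 1 rose, Cyp26a1, which degrades retinoic acid, at 1.36, and 3 fell, with Fst, a follistatin, at -1.45 as the third. That list was lower by camera (median -0.14; adjusted p = 0.0269), with adjusted p = 0.618 with an estimated correlation, and its adjusted p was 0.250 with members held by another list left out, 0.0974 with the mean of all probe sets of a gene, 0.151 without f/f 1 and 0.124 without d/d 3. Pgr and Esr1, the receptors of progesterone and estrogen, had log2 differences of -0.28 ± 0.21 and -0.063 ± 0.091 (SE) and did not pass. Without single arrays Ihh was called 3 of 6 times, Gli1 3 of 6 and Ptch1 1 of 6, with adjusted p up to 0.0634, 0.0635 and 0.173.

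**Figure D1:**
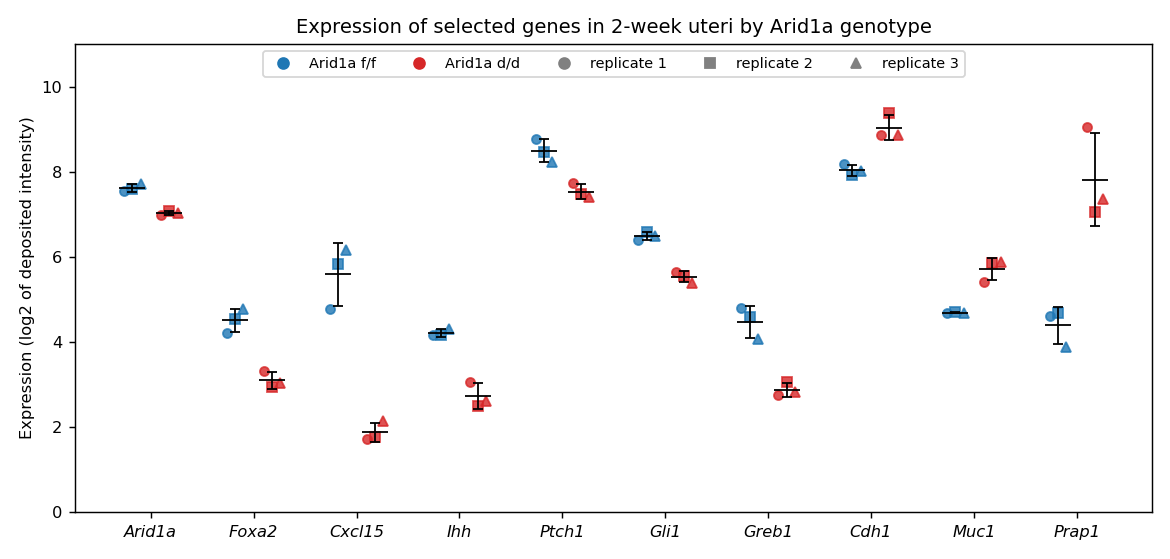
Log2 intensity of 10 named genes in each of the 6 arrays, with f/f in blue and d/d in red and a marker shape per replicate number. Black bars give the mean and SD of 3 arrays. Foxa2, Cxcl15, Ihh, Ptch1, Gli1 and Greb1 lie lower in every d/d array than in every f/f array, while Cdh1, Muc1 and Prap1 lie higher.

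Muc1 and Cdh1, 2 general epithelial genes, were higher in d/d uteri. Muc1, a cell surface mucin, rose by a log2 difference of 1.03 ± 0.13 and Cdh1, the epithelial cadherin, by 1.00 ± 0.15 (SE; limma adjusted p of 0.0178 and 0.0314). Of 15 measured markers of simple epithelium 1 rose, 0 fell and 14 did not pass, and adjusted over the list alone 8 rose and 0 fell. Krt18 and Krt8, keratins of simple epithelium, had log2 differences of 0.62 and 0.61, and Cldn7, a claudin, 0.62, while 4 of the 15 were lower: Calb1 (-1.21), Ehf (-0.53), Prom1 (-0.22) and Cldn3 (-0.18). The list was higher by camera (median 0.43; adjusted p = 1.42e-05), with adjusted p = 0.453 with an estimated correlation. Of 24 measured genes tied to gland formation and Müllerian patterning, each by its brightest probe set, 1 rose (Cdh1) and 1 fell (Foxa2), and adjusted over the list alone 4 rose and 3 fell. A dimmer probe set of Fgfr2, another member, rose by 1.02 (limma adjusted p = 0.00869 over probe sets). Wnt16 and Wnt7a, Wnt ligands, stood at 0.74 and 1.39, and Wnt7a at 0.44 with the mean of its probe sets. That list did not pass camera (adjusted p = 0.131, and 0.475 with an estimated correlation). Camera gave 0.00625 upward with the 4 members held by another list left out: Foxa2, the largest fall of the list, Lef1, Hoxa10 and Wnt4. Without single arrays Muc1 and Cdh1 were each called 1 of 6 times, with adjusted p up to 0.0967 and 0.151.

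Across the array, 192 of 16813 genes differed, 106 higher and 86 lower in d/d uteri, and 217 of 41420 probe sets, 130 higher and 87 lower. All 192 genes had groups that did not overlap, which chance gives for 10% of genes with 3 against 3 and which held for 16.5% of all genes. The largest rise among the named genes was that of Prap1, a secreted proline-rich protein, at 10.8-fold (log2 difference 3.43 ± 0.49 SE; limma adjusted p = 0.0251). Without d/d 1 its log2 difference was 2.81, and it was called in 1 of 6 fits with 1 array left out. Cers3, a ceramide synthase, rose 4.33-fold, and Upk3bl, a uroplakin-like gene, 4.11-fold. H60c, a ligand of the receptor NKG2D, rose 4.73-fold over genes but had an adjusted p of 0.0503 over probe sets. With an intensity trend and robust variance Prap1 and H60c had adjusted p of 0.0708 and 0.0635. Log2 rises of 1.75 to 1.41 were found for Mpzl2 (1.75), Cyp4x1 (1.74), Prr15 (1.63), Ptprr (1.61), Crybg1 (1.58), Bcl11a (1.56), Sema3e (1.56), Il17re (1.53), Dzank1 (1.52), Vwc2 (1.45) and Gpat3 (1.41). Prap1 and Mpzl2 each have 1 probe set, with the suffix _x_at, and so no value when such probe sets are left out. Vwc2 rested on one too, and its other probe set gave 0.044. Of 7 Bcl11a probe sets 3 passed, and of 3 Prr15 probe sets 1, with the other 2 at 0.40 and -0.12. The Vwc2 probe set at 0.044 and the Prr15 probe set at -0.12 lay below 2.69 in both genotypes, where background limits what they can show. The mean of all probe sets, which includes these, gave 0.79 for Bcl11a, 0.64 for Prr15 and 0.74 for Vwc2.

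Fam107a fell 15.9-fold by its brightest probe set (log2 difference -3.99 ± 0.57 SE; limma adjusted p = 0.0242), and 4.98-fold and 1.54-fold by its other 2. The brightest probe set of Fam107a stood at 4.31, 1.82 and 2.27 in d/d 1, 2 and 3. Its values in d/d 2 and d/d 3 lay below 2.69, where background limits the fold. The mean of all its probe sets gave a log2 difference of -2.31, against -2.96 for Cxcl15. Without d/d 1 the brightest probe set gave -4.75, and it was called in 1 of 6 fits with 1 array left out. Them5, a thioesterase, fell 5.59-fold, to a d/d mean of 2.02 that also lay below 2.69, and Lrp2, the endocytic receptor megalin, 4.99-fold. Slc2a3, a glucose transporter, fell 5.13-fold, Pck1, an enzyme of gluconeogenesis, 3.55-fold, and Hk2, a hexokinase, 3.36-fold. Greb1, an estrogen-responsive gene, fell 3.04-fold. Further log2 differences were -1.62 for Rassf5, -1.41 for B3gnt5, -1.36 for Slc14a1, a urea transporter, -1.30 for Gkn3, by an _x_at probe set with its other at -1.74, and -1.25 for Dner. The mean of all probe sets ended the calls of Slc2a3 and Slc14a1, each at -1.21 with adjusted p of 0.0713 and 0.104. Of the 4 Slc2a3 probe sets, 2 gave -0.065 and 0.031, and both lay below 2.69 in both genotypes, where background limits the fold. The mean of all probe sets gave -1.43 for Them5, -1.59 for Lrp2, -0.67 for Pck1, -0.84 for Greb1 and -0.82 for B3gnt5. With an intensity trend and robust variance Fam107a and Slc2a3 had adjusted p of 0.0700 and 0.101. Over probe sets Slc2a3 and Slc14a1 had adjusted p of 0.0511 and 0.0531, and 2 of the 4 Greb1 probe sets and 1 of the 3 Pck1 probe sets passed. The Greb1 and Pck1 probe sets that did not pass lay below 2.69 in both genotypes. With 1 array left out, the count of genes past the threshold was 83 without f/f 1, 26 without f/f 2, 35 without f/f 3, 821 without d/d 1, 36 without d/d 2 and 33 without d/d 3. Of the 31 named genes, 8 passed without each array: Cers3, Mpzl2, Cyp4x1, Prr15, Bcl11a, Cxcl15, Them5 and Rassf5.

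The fat, endothelium, stroma, smooth muscle and lymphocyte lists were lower in d/d samples, although 1 of their markers passed over all genes. All 8 measured fat cell markers were lower (median -0.91; camera adjusted p = 4.48e-06), with adjusted p = 0.453 with an estimated correlation. Adjusted over the list alone 7 fell, among them Adipoq, the adiponectin gene, at -1.59 ± 0.37, and Retn, the resistin gene, at -1.46 ± 0.33 (SE). A dimmer probe set of Fabp4, another fat marker, fell by 0.54 (limma adjusted p = 0.0314 over probe sets). It lay below 2.69 in both genotypes. All 9 endothelial markers were lower (median -0.47; adjusted p = 2.74e-06), with adjusted p = 0.453 with an estimated correlation, and 5 fell adjusted over the list alone, with Cdh5, a cadherin of endothelium, at -0.75 and Esam at -0.71. Of 16 stromal markers 1 fell, Thy1, at -1.06 ± 0.13 (SE; limma adjusted p = 0.0155). Adjusted over the list alone 1 rose, Vcan, the versican gene, at 0.69, and 2 fell, Thy1 and Mmp2, a matrix protease, at -0.45, while Dcn, the decorin gene, stood at -0.76. The stroma list was lower (median -0.24; adjusted p = 0.00129), with adjusted p = 0.475 with an estimated correlation. Thy1 was called in 2 of 6 fits with 1 array left out, with adjusted p up to 0.0856. Smooth muscle genes (median -0.15, with Des at -0.46; adjusted p = 0.0272) had adjusted p = 0.743 with an estimated correlation. For smooth muscle the adjusted p was 0.151 without f/f 1, 0.134 without f/f 3, 0.466 without d/d 2 and 0.1001 without d/d 3. Lymphocyte genes (median -0.20, with Cd3d at -0.36; adjusted p = 0.0272) had adjusted p = 0.453 with an estimated correlation. For lymphocytes it was 0.0596 without f/f 3, 0.0777 without d/d 1, 0.0673 without d/d 2 and 0.0542 without d/d 3.

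**Figure D2:**
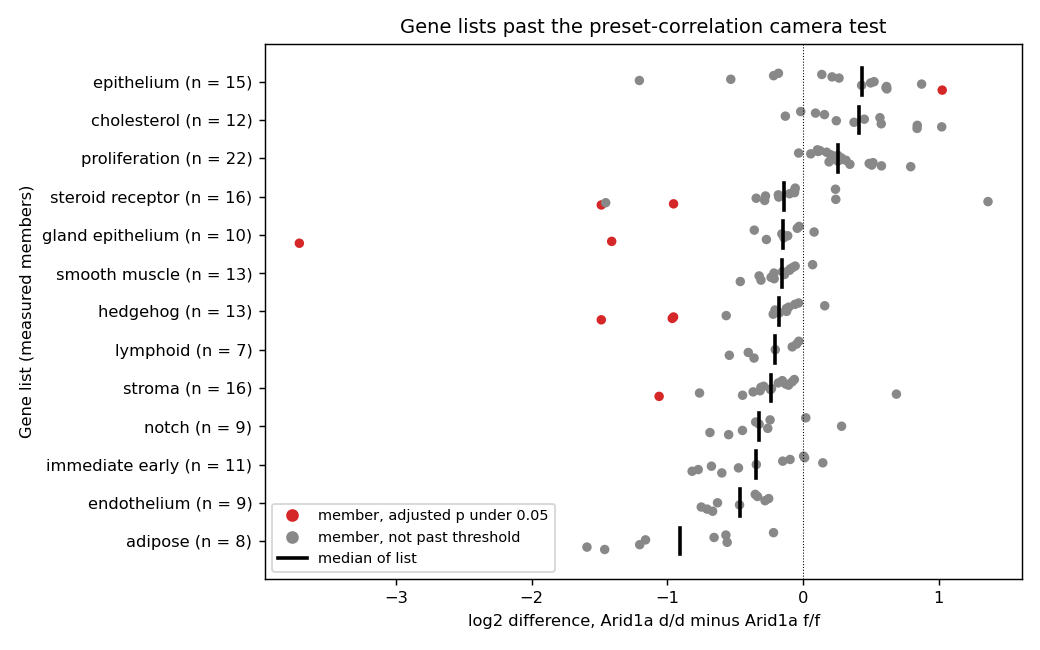
Log2 difference, d/d minus f/f, of every measured member of the 13 gene lists past the camera test with a preset correlation. Each point is a gene, red where its adjusted p over all genes is under 0.05, and the black bar is the list's median. The medians run from -0.91 for fat cell markers to 0.43 for epithelial markers.

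Cell state and signalling lists differed too. Of 12 measured genes of cholesterol synthesis and uptake, 0 passed over all genes and 1 rose over the list alone, with Fdft1, a squalene synthase, at 0.84 and Idi1, an isomerase, at 1.02. The list was higher (median 0.41; camera adjusted p = 0.00130), with adjusted p = 0.618 with an estimated correlation. Of 9 Notch pathway genes 0 passed over all genes and 4 fell over the list alone, with Heyl, a target gene, at -0.69 and Jag2, a ligand, at -0.55. The Notch list was lower (median -0.32; adjusted p = 0.00469), with adjusted p = 0.618 with an estimated correlation, and had adjusted p of 0.0695 without f/f 1 and 0.0505 without d/d 3. Of 11 immediate early and heat shock genes, which also respond to tissue handling, 0 passed over all genes and 3 fell over the list alone, with Egr2 at -0.60 and Ier3 at -0.82. That list was lower (median -0.34; adjusted p = 0.00756), with adjusted p = 0.618 with an estimated correlation, and had an adjusted p of 0.0822 without d/d 3.

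Cell cycle genes were higher as a list (22 measured, median 0.26; camera adjusted p = 0.0307), with adjusted p = 0.743 with an estimated correlation, and 0 passed over all genes or over the list alone. Mcm6, a helicase subunit of DNA replication, had a log2 difference of 0.79 ± 0.35 (SE). The list's mean level was 5.21, 5.41 and 6.18 in f/f 1, 2 and 3 and 4.80, 6.51 and 6.34 in d/d 1, 2 and 3, so arrays of 1 genotype differed by more than the genotypes did. The list's adjusted p was 0.407 without f/f 1, 0.211 without f/f 2, 0.863 without d/d 2 and 0.450 without d/d 3, and 0.0861 without _x_at and 0.0502 without dim probe sets. Array f/f 1 correlated best with d/d 1 over all probe sets (0.995). In turn, d/d 1 correlated more closely with each f/f array (0.991 to 0.995) than with d/d 2 (0.9901) or d/d 3 (0.9905). On the first principal component, the axis of largest variance (42.6%), d/d 1 at -11.9 lay among the f/f arrays. These lay at -29.4, -17.7 and -6.95, while d/d 2 and d/d 3 lay at 37.2 and 28.8. The fat list's mean was 5.24, 5.05 and 5.69 in f/f 1, 2 and 3 and 4.84, 4.07 and 4.28 in d/d 1, 2 and 3.

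**Figure D3:**
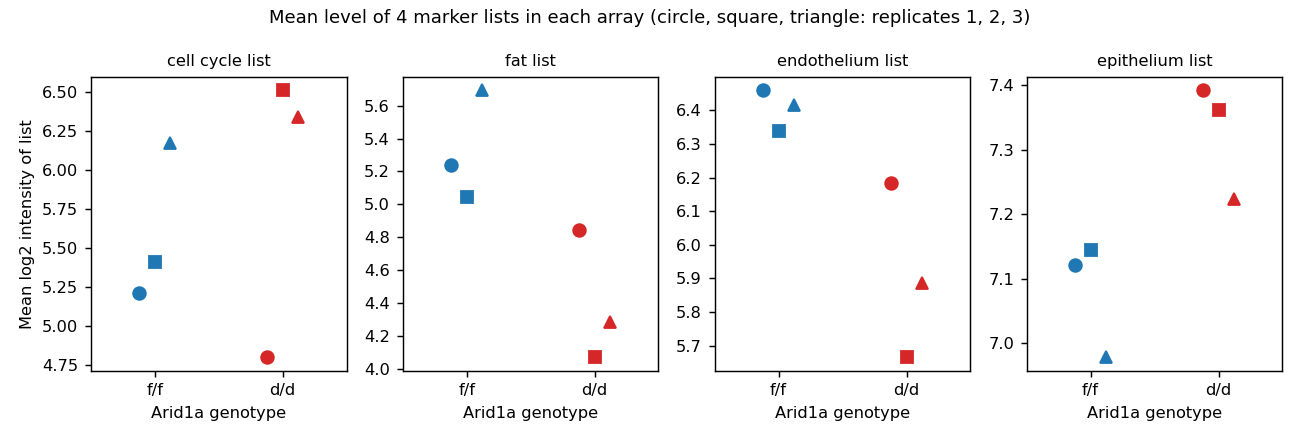
Mean log2 intensity of the cell cycle, fat, endothelium and epithelium lists in each array, with f/f in blue and d/d in red. Each point is 1 array and its shape gives the replicate number. The cell cycle list runs from 4.80 in d/d 1 to 6.51 in d/d 2, and each vertical axis has its own range that does not start at 0.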

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

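Leaving out both arrays numbered 1 and the covariates for cell cycle and fat genes were chosen after seeing the data. All 192 genes past the threshold kept their direction in every setting that tested them, and the median of all genes moved by under 0.1 in each. As the groups of these 192 genes did not overlap, leaving out arrays could not reverse a direction, so that outcome was fixed in advance. The replicate numbers were not taken to pair the arrays, as 1 of 3 correlations lay under 0.1: the deviations of same-numbered arrays correlated at 0.461, 0.0228 and 0.178, and f/f 2 went best with d/d 3 (0.160) and f/f 3 with d/d 2 (0.299). With the replicate number as a block, 574 probe sets (295 higher, 279 lower) and 457 genes (217 higher, 240 lower) passed, including 191 of the 192, and the block changed no list's call. Array weights gave 329 probe sets, with 147 lower, and 133 genes lower, and kept all 192. The mean of all probe sets of a gene kept 144 of the 192. Leaving out both arrays numbered 1 gave 657 probe sets (298 higher, 359 lower) and 540 genes (221 higher, 319 lower), and kept 172 of the 192, Arid1a among them; over probe sets Arid1a stood at -0.59 with an adjusted p of 0.0595. The cell cycle covariate gave 611 probe sets (328 higher, 283 lower) and 534 genes (263 higher, 271 lower). The fat covariate gave 0 probe sets and 0 genes in either direction, with Arid1a at -0.56, because the fat list mean correlates with genotype at -0.84 and standard errors grew. It reversed, with neither side past the threshold, Smtn (0.23), Tagln (0.045), Mylk (0.21), Fabp4 (0.15), Pparg (0.065), Smarca2 (0.21), Ndufa4 (-0.15), Ndufb8 (-0.029) and B2m (0.16). An adjusted p under 0.10 gave 462 probe sets (256 higher, 206 lower) and 403 genes (198 higher, 205 lower), and an unadjusted p with a fold of 1.5 gave 842 probe sets (420 higher, 422 lower). Both follow from the looser threshold; apart from these and the fat covariate the cause was not tested.

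With each array left out in turn, probe sets ranged from 37 to 971 (higher 21 to 410, lower 16 to 561), genes from 26 to 821 (higher 16 to 328, lower 10 to 493), lists from 7 to 13 and Arid1a from -0.62 to -0.53. Of the 192 genes, 69 stayed past the threshold without f/f 1, 25 without f/f 2 and 33 without f/f 3. Without d/d 1, d/d 2 and d/d 3 the numbers kept were 192, 36 and 32. Adjusted p ranges for lists whose call changed were 1.43e-04 to 0.466 for smooth muscle, 0.0131 to 0.0777 for lymphocytes, 0.0490 to 0.625 for mesothelium, 0.00365 to 0.151 for steroid receptors, 9.22e-11 to 0.863 for cell cycle, 0.0286 to 0.325 for Wnt targets, 3.67e-04 to 0.0695 for Notch, 1.03e-05 to 0.0822 for immediate early genes and 0.0246 to 0.792 for the respiratory chain. Reversals without single arrays, all with neither side past the threshold, lay in the ranges 0.469 to 0.969 for ciliated, 0.151 to 0.881 for squamous, 0.477 to 0.943 for SWI/SNF, 0.456 to 0.969 for retinoid, 0.325 to 0.971 for interferon and 0.790 to 0.966 for glycolysis, and Alas2 ranged from -0.66 without f/f 3 to 0.012 without f/f 1.

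With the correlation estimated per list 0 lists passed, with adjusted p of 0.453 for gland epithelium, epithelium, endothelium, lymphocytes, fat and hedgehog, 0.475 for stroma, 0.618 for steroid receptors, Notch, immediate early genes and cholesterol, and 0.743 for smooth muscle and cell cycle. Fry gave 0 lists, with adjusted p of 0.0543 for gland epithelium, epithelium and lymphocytes, 0.0645 for hedgehog, 0.132 for endothelium, 0.152 for stroma and fat, 0.204 for steroid receptors, 0.236 for Notch, 0.351 for immediate early genes, 0.420 for cholesterol, 0.493 for smooth muscle and 0.773 for cell cycle. It reversed ciliated (0.957), SWI/SNF (0.775) and glycolysis (0.351). With members held by another list left out, gland development passed (0.00625), gland epithelium (0.250) and steroid receptors (0.250) did not, and glycolysis reversed (0.854). That setting removes Foxa2 and Cxcl15 from gland epithelium and Ihh and Ptch1 from steroid receptors, their only members past the threshold over all genes. Without dim probe sets the cell cycle list had 0.0502 and ciliated reversed (0.896), without _x_at probe sets cell cycle had 0.0861 and glycolysis reversed (0.862), glycolysis also reversed without both arrays numbered 1 (0.843), and the mean of all probe sets left steroid receptors at 0.0974. Probe sets near background limit the folds of dim genes.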

Other observations

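The tests on fat cells, the share of epithelium, the cell cycle level and shared litters were chosen only after the results they bear on had been seen. The test on other splits of the arrays was set before its outcome was seen. Those on FGF feedback genes and junction genes were also set before their own outcomes were seen. Their hypotheses, however, came from gene values already seen in the same arrays, so they were not prior predictions. For fat cells and for the cell cycle level a second test was chosen after the outcome of the first was known, and both outcomes are given.

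Several further lists did not pass camera but held single genes past the threshold over all genes, while the Wnt target list held none. Bmp4, a BMP ligand, fell by 1.18 ± 0.17 on the log2 scale (SE; limma adjusted p = 0.0260), 1 of 20 measured BMP and TGF-beta genes that passed over all genes, and 3 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.520). Aldh1a2, which makes retinoic acid, rose by a log2 difference of 0.70 ± 0.10 (SE; limma adjusted p = 0.0235), 1 of 13 retinoid genes, with Rbp4, a retinol carrier, at -1.31, and 2 rose and 3 fell over the list alone (adjusted p = 0.855). Without single arrays, Bmp4 and Aldh1a2 were each called 1 of 6 times. Among 20 Wnt target genes 0 passed over all genes, and over the list alone 1 rose, Lgr5, at 1.40 ± 0.29 (0.73 with the mean of its probe sets), and 4 fell, among them Wif1 at -0.62 and Lef1 at -0.56 (adjusted p = 0.131, and 0.0286 without f/f 2). Of 12 estrogen-responsive genes 1 rose (Muc1) and 2 fell (Cxcl15 and Greb1), with Igf1 at -0.39, and over the list alone 1 rose and 3 fell. The estrogen list's median was 0.042 while its mean was -0.32 and camera pointed down (adjusted p = 0.501). Hk2 was the 1 of 15 glycolysis and hypoxia genes that fell, and Pdk1 stood at 0.40 (adjusted p = 0.936). Arid1a was the 1 of 24 SWI/SNF subunits that passed, with Arid1b at 0.20 and Bcl7a at 0.32 (adjusted p = 0.830).

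Other lists had 0 members past the threshold over all genes and did not pass camera. Of genes of epithelial-mesenchymal transition 2 rose and 2 fell over the list alone, with Cdh2 at 0.87 and Twist2 at -0.65 (adjusted p = 0.520). Matrix remodelling genes had 1 higher and 3 lower over the list alone, with Col4a2 at -0.48 (adjusted p = 0.178), and interferon genes 3 higher and 1 lower, with Rsad2 at -0.89 (adjusted p = 0.883). Myeloid markers had 1 higher and 1 lower over the list alone, with Cd68 at 0.46 and S100a8 at -0.50 (adjusted p = 0.250). No member passed over the list alone for the cell cycle arrest (adjusted p = 0.376), respiratory chain (0.218, with 0.0293 without f/f 3 and 0.0246 without d/d 1), loading reference (0.587), skeletal muscle (0.218), red blood cell (0.245), mesothelium (0.225, with 0.0490 without d/d 2), nerve (0.655), squamous (0.637), ciliated (0.880) and ovary (0.846) lists. Median, mean and camera direction differed in sign for squamous, ciliated, ovary, SWI/SNF and glycolysis genes.

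Fat markers moved together between arrays of 1 genotype, with a mean pairwise correlation of their deviations of 0.602. A varying amount of fat tissue would give this, but it is not particular to fat, since the cell cycle (0.910), cholesterol (0.708), smooth muscle (0.695), red blood cell (0.619) and immediate early (0.610) lists had higher values. In the first test of whether fewer fat cells may account for the genes lower in d/d, the 493 genes called lower without d/d 1 showed in that array a median 34.2% of their fall (quartiles 5.37% and 60.02%), against 42.2% for the fat list, which decides nothing, as genes picked by their difference in the other arrays show a smaller share in a left-out one whatever the cause. In the second, with the fat list mean as a covariate, 82.3% of the median fall of the 86 genes remained (quartiles 70.1% and 96.1%), and the median log2 difference went from -0.83 (median SE 0.12) to -0.69 (median SE 0.21). As the fat mean correlates with genotype at -0.84, which raised the standard errors, and 0 of 86 genes stayed past the threshold, an effect of fat tissue on the lower genes and an effect of genotype cannot be told apart.

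A larger share of epithelium in the d/d samples could raise epithelial markers and lower those of other cell types. It would not lower Foxa2, which is made in epithelium and had a log2 difference of -1.41. Of 15 epithelial markers, 7 lay over 2 standard errors from the list's median, 2 above it and 5 below. This does not decide whether a larger share is the whole cause of the higher epithelial list. Differences at the dim end are compressed, so markers may rise unequally under a larger share. A larger share would not lower epithelial markers, and 4 of the 15 were lower, but 0 fell adjusted over the list alone. The median log2 difference of endothelial markers minus that of smooth muscle markers was -0.32 (SE 0.14 over members), where a larger epithelial share alone would lower both alike. An SE of 0.034 over arrays belongs to the same comparison made with list means in place of medians. A larger epithelial share as a cause of the higher epithelial list, in whole or in part, and a biological effect of the genotype on each cell type stay open.

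Cell cycle genes varied between arrays of 1 genotype, and no biological explanation of the variation was tested. The list mean lay below that of its genotype in both arrays numbered 1, above it in both numbered 3 and on opposite sides in those numbered 2. Over all probe sets the deviations of same-numbered arrays correlated at 0.461, 0.0228 and 0.178, so a litter or batch shared by some numbers stays open. In the first test of whether the state of d/d 1 makes the calls, 674 of the 821 genes called without that array, or 82.1%, lay on the called side of the f/f mean in it, against a bound of 80% set for rejecting the explanation, which excludes nothing, as it rests on 1 array and on genes picked in the others. In the second, all 192 genes stayed past the threshold with the same direction when the cell cycle list mean was a covariate, with 98.3% of the median change left. That mean correlates with genotype at only 0.224, and the 192 genes were picked by their difference between the genotypes. The covariate could therefore hardly end their calls, and the test does not decide whether the cell cycle level plays a part.

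The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For probe sets, for genes and for lists, 1 of the 10 splits, the real one, gave as many calls. The real values were 217, 192 and 13, and the highest of the others 14, 74 and 11. The split of f/f 1, f/f 2 and d/d 1 from the rest, which follows the level of cell cycle genes, gave the 14 and the 74, with 9 lists. The remaining splits gave 0 probe sets and 0 genes, but 11, 10, 9, 3, 2, 1, 1 and 0 lists. Camera with the preset correlation thus called nearly as many lists in some arbitrary splits, so the number of lists past it says little about genotype.

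Etv5 and Il17rd, both tied to FGF and ERK signalling, fell by 0.92 and 0.75 on the log2 scale. Over probe sets Il17rd passed (limma adjusted p = 0.0444) and Etv5 did not. Their values led to the hypothesis that feedback genes of this signal are lower as a group. It was not borne out: over 10 other measured feedback genes, 5 higher and 5 lower, camera gave a p of 0.972. Over the list alone 1 passed, Spry2, which rose by 0.42, while Spsb1 stood at -1.32 ± 0.59 (SE). Spry3, Etv4 and Spred3 lay below 2.69 in both genotypes, where background limits any fall, so the test was weak. Cgn, Ocln, Marveld2 and Dsp, genes of epithelial junctions, rose by 0.93, 0.65, 0.76 and 0.90. Over probe sets Cgn, Marveld2 and Dsp passed (limma adjusted p of 0.0291, 0.0251 and 0.0198) and Ocln did not. Their values led to the hypothesis that junction genes may be higher as a group. Over 20 other measured junction genes camera gave a p of 2.49e-04 upward and a p of 0.0170 with an estimated correlation, with a median of 0.21. Neither p was adjusted over lists, and the hypothesis came from the same arrays. With an estimated correlation the epithelium list had an unadjusted camera p of 0.0280 and an adjusted p of 0.453. Of the 20 junction genes 0 passed over all genes by their brightest probe set, and a dimmer Dsg2 probe set rose by 0.70 (limma adjusted p = 0.0418 over probe sets). Over the list alone 6 rose, among them Llgl2 at 0.62 and Pard6b at 0.79, and 1 fell, Cldn1, at -0.70. The larger share of epithelium weighed above stays an open explanation for this group.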
